A study of Arabidopsis thaliana with 4 samples.

How the data were processed

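The 4 RNA-seq libraries were made from whole 14-day-old seedlings of Arabidopsis thaliana, ecotype Col-0. Per the labels' protocols, the seedlings grew hydroponically on a basal salt mixture without nitrogen and were then moved to the same mixture with 2.5 mM glutamate. Libraries were built from Trizol-extracted total RNA with the Illumina TruSeq RNA kit, per the labels' protocols. There were 2 libraries from 0 h and 2 from 0.5 h of glutamate, and all 4 carry the same batch label. No library came from seedlings moved for 0.5 h to medium without glutamate, so the move and the elapsed time differ between the groups together with glutamate. The labels do not say whether the 2 libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

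The deposited table holds 33602 genes with 1 RPKM value per library, a gene length in kilobases and a column named maxMultiRatio. Per the submitters' processing notes, reads were placed on TAIR10 and SAMtools was used. The aligner, the counting tool, the use of strand and the versions are not given in the sources used here. The authors' RPKM values were taken apart before use. In each library the value times the length has a lowest level shared by over 10000 genes, and the other levels lie at whole odd multiples of it, so that the deposited value equals reads plus 0.5, divided by the length and by an effective library size. Reads recovered this way were whole, within 0.01, for at least 99.9% of the genes with a maxMultiRatio of 0 and for 85.3% to 86.2% of all genes. The deposited maxMultiRatio is a fraction between 0 and 1 that the file header does not define. It was read as the share of a gene's reads that also match elsewhere, because recovered reads were whole where it is 0. Genes with a high fraction are reported as uncertain. The effective library size was 1.04 and 1.06 times the recovered reads in the control libraries and 0.907 and 0.932 times in the glutamate libraries, and the deposited table is labelled as TMM normalization (trimmed mean of M-values).

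Recovered reads came to 27674435 and 23669908 in the control libraries and to 21776595 and 24599752 in the glutamate libraries. At that depth 3 reads in a gene of 1 kb are worth 0.104 to 0.152 RPKM. For a group without reads, 3 reads at the gene's own length, averaged over the libraries of the group, served as the floor. Floors cover counting error only. The 2 libraries of a group were compared before they were averaged: over genes with at least 20 reads, the chi-square per degree of freedom was 31.7 between the control libraries and 27.1 between the glutamate libraries, so that neither pair agreed within counting noise. This does not show whether they came from separate cultures.

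Values were transformed to log2(RPKM + 1), and the 17750 genes with a mean over the 4 libraries of at least 1 RPKM were tested with limma 3.58.1 in R 4.3.3, with a variance prior that follows intensity, two-sided, and Benjamini-Hochberg adjustment. A gene was called at an adjusted p under 0.05. Log2 changes, their ranks and the 2-fold threshold are on the log2(RPKM + 1) scale, which understates the change of low genes, while the bound for ATCG01180 is a ratio of RPKM to the floor. With 2 residual degrees of freedom the test draws on the variance of all genes, through a prior worth 3.49 degrees of freedom. An exact permutation test of 2 against 2 libraries cannot give a p under 0.33, so none was run for single genes. Reads were simulated for independent libraries with 1 dispersion for all genes, 0.0127, a median over well-covered genes of these replicates. On them the same steps called 9 of 17740 genes where nothing changed. The steps recovered 92.3% of genes changed 2-fold and 100.0% of genes changed 4-fold. In the 2-fold simulation, 32 of the 212 calls were false, and in the 4-fold simulation 21 of 212, more than the nominal rate. In the data the spread varies between genes, libraries with the same replicate number deviated together (r = 0.60) and far more genes were called. The simulated rates therefore need not hold for the data.

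Before the data were examined, 26 gene lists with 426 entries were fixed. They covered nitrate response, nitrogen starvation, glutamate metabolism, glutamate receptor-like genes, amino acid transporters, jasmonate, ethylene and ERF factors, pattern-triggered immunity, salicylate, indole and camalexin, touch, calcium sensors and pumps, abscisic acid and drought, cold, heat, hypoxia, detoxification, auxin, cytokinin, sugar starvation, ribosome biogenesis, circadian clock, shoot photosynthesis markers, root markers, guard cell and vascular markers, and control genes. Matching by symbol or identifier to the TAIR10.1 gene table found 424 entries, and 32835 of the 33602 identifiers in the file were in that table. Lists share genes: 6 of the 11 touch genes were also in the calcium or immunity list. Each list was tested with limma's camera at a preset correlation of 0.01, two-sided, adjusted over the 26 lists. Camera with a correlation estimated per list, and fry, were alternatives. The estimated version judges a list with only the 2 residual degrees of freedom, so few lists can pass it. A list count is also given adjusted over the list alone. Counts are out of tested members. Below the minimum mean, and so untested, were, among others, 6 of 18 salicylate, 8 of 17 root, 8 of 18 nitrogen starvation, 5 of 20 receptor-like and 4 of 11 auxin genes. The mean is over all 4 libraries, so a gene low at 0 h can be tested through its glutamate level. Genes low in both groups drop out, so the shares called hold for tested members only.

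The rule for named genes was fixed at the same time. It took the 8 largest rises and 8 largest falls among called genes with separated libraries and a mean of at least 2 RPKM, and up to 3 called members of each list with the smallest p. Control genes and glutamate receptor-like genes could be named whether or not they passed. Genes outside this rule are said to be chosen after their values were seen. The reference served only for names, product names and intron numbers. The gene length in the file equals a TAIR10.1 transcript length for 11262 of 32827 loci. The annotations or the definitions of gene length thus differ, and no coordinates are given. Loci without a symbol in that table are given by identifier.

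Alternatives planned before the data were examined were another pseudocount (0.1 or 5), no filter or a mean of at least 5, quantile normalization, setting the median log2 ratio to 0, a replicate block, a prior without trend or a robust one, leaving out each library, and stricter thresholds. Added after seeing the data were no further pseudocount, scaling to the library totals, centring on the control genes, leaving out genes with a maxMultiRatio above 0.1, and voom weights on the recovered reads. Product-name families and intron numbers were analysed with Python 3.11.15 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.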

Results

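The series asked which Arabidopsis genes respond early to glutamate. Seedlings of the Col-0 ecotype, grown for 14 days without nitrogen, were sampled at 0 h and after 0.5 h in medium with 2.5 mM glutamate, with 2 RNA-seq libraries per group. The control libraries held 27674435 and 23669908 recovered reads and the glutamate libraries 21776595 and 24599752. The 10 most abundant genes took 7.09% and 6.98% of the control reads and 5.48% and 5.13% of the glutamate reads. Transcripts encoded in the chloroplast made up 0.0419% and 0.0559% of the control reads and 0.0426% and 0.0437% of the glutamate reads, and those of the mitochondrion at most 0.0167%. Across genes, which are not independent replicates, log2 values correlated at 0.983 or more between libraries of one group and at 0.878 or less between groups.

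The 8 largest rises after 0.5 h of glutamate, ranked on the log2(RPKM + 1) scale among called genes with a mean of at least 2 RPKM, were 6.75 to 7.99, and their genes encode, among others, a calcium sensor, cell wall proteins and transcription factors. The calmodulin-like gene CML37 (AT5G42380) rose from 2.24 ± 0.78 to 811 ± 62.7 RPKM (SD, n = 2), a log2 change of 7.99 ± 0.19 (SE). AGP1 (AT5G64310), which encodes an arabinogalactan protein of the cell surface, rose from 3.52 ± 0.69 to 798 ± 168 RPKM. XTH18 (AT4G30280), a xyloglucan-modifying enzyme of the cell wall, went from 13.3 ± 2.98 to 1898 ± 248 RPKM, and the mitochondrial dicarboxylate carrier UCP5 (AT2G22500) from 6.97 ± 1.93 to 946 ± 14.7 RPKM. The transcription factor genes ZAT7 (AT3G46090) and WRKY46 (AT2G46400) rose by 6.87 ± 0.12 and 6.81 ± 0.14 on the log2 scale, to 541 and 507 RPKM. The locus AT1G15010 rose from 4.30 to 551 RPKM. MSRB7 (AT4G21830), a methionine sulfoxide reductase gene, rose from 0.491 to 285 RPKM. Its shared-read fraction of 0.266 and its control reads of 18.1 and 3.4 leave its levels uncertain. The adjusted p of these 8 genes in limma lay between 3.82e-05 and 8.12e-05.

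In all, 2888 genes were higher and 2585 lower at an adjusted p under 0.05 in limma, 30.8% of the 17750 tested. In each of the 5473 called genes both glutamate libraries lay on the same side of both control libraries. Selection by a small p nearly forces this, so it adds no support to the calls. The rises were larger than the falls: 1829 of the higher genes and 844 of the lower genes changed at least 2-fold, and 365 rose but 10 fell by at least 3 on the log2 scale. The split depended on scaling. Higher genes made up 52.8% of calls as deposited, 35.8% when libraries were scaled to their totals (2433 higher, 4364 lower) and 66.4% when centred on the control genes (3316 higher, 1675 lower). The median log2 change of all tested genes was -0.06 as deposited, -0.23 with library totals, -0.15 with quantile normalization and 0.07 with the control genes, so changes of about that size are not given a direction here.

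**Figure D1:**
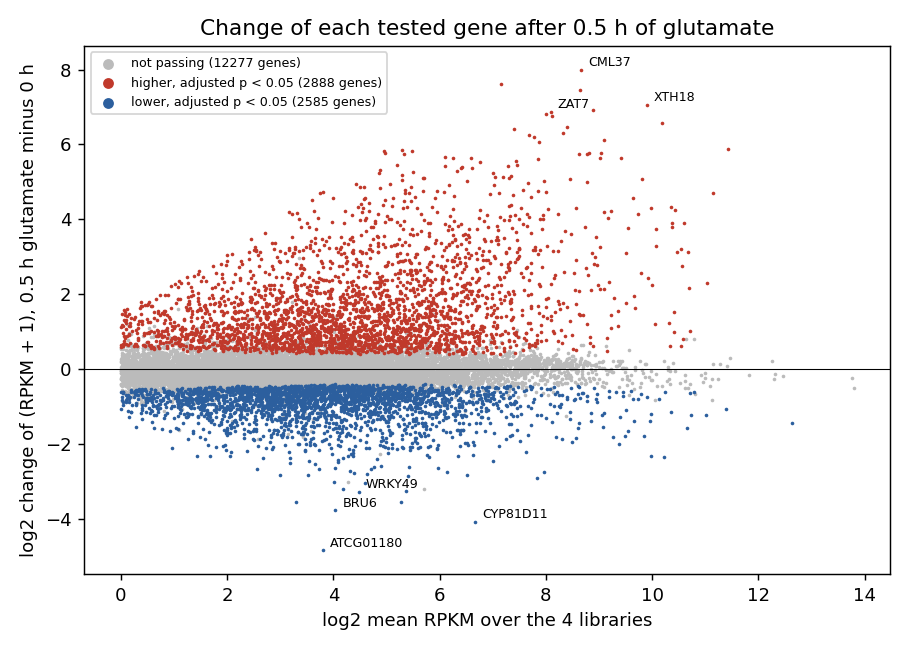
Log2 change of RPKM + 1 between 0.5 h of glutamate and 0 h (vertical) against log2 mean RPKM over the 4 libraries (horizontal), with 1 point per tested gene and called genes in red (2888 higher) and blue (2585 lower). The rises reach 7.99 and the falls 4.84 in size, and the lowest point, ATCG01180, is a locus whose reads are shared.

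The 8 largest falls on the same scale included genes of a cytochrome P450, of enzymes that conjugate auxin or other small molecules, and of a transcription factor. CYP81D11 (AT3G28740), the P450 gene, fell from 193 ± 15.2 to 10.5 ± 2.1 RPKM, a log2 change of -4.08 ± 0.17. The auxin-conjugating enzyme gene BRU6, also known as GH3.2 (AT4G37390), fell from 31.5 ± 6.14 to 1.36 ± 0.17 RPKM, and the glucosyltransferase genes UGT73C1 (AT2G36750) and IAGLU (AT4G15550) from 18.9 and 72.5 to 0.693 and 5.30 RPKM. IAGLU had a shared-read fraction of 0.109. WRKY49 (AT5G43290), a transcription factor gene, fell from 41.1 ± 0.41 to 3.35 ± 0.02 RPKM. The loci AT4G29905 and AT5G54585 fell from 75.4 and 33.7 to 6.94 and 2.73 RPKM. The chloroplast locus ATCG01180 had 2237 and 1978 reads in the control libraries and 0 in both glutamate libraries. Its mean control level was 553-fold above the mean floor of 3 reads per glutamate library at its own length. All of its reads are shared with another locus, so this value is uncertain.

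All 16 members of the list of calcium sensors and pumps were higher, with log2 changes from 1.15 to 7.99 and a median of 3.72 (camera adjusted p = 1.08e-13, adjusted p = 0.271 with an estimated correlation; 16 higher adjusted over the list alone). CML38 (AT1G76650), another calmodulin-like gene, rose from 23.2 ± 4.52 to 2312 ± 240 RPKM, and CML40 (AT3G01830) from 4.92 ± 0.58 to 433 ± 39.7 RPKM. Touch-responsive genes, known to react to mechanical stimulation, were higher in 10 of 11 cases, with a median log2 change of 3.58 (camera adjusted p = 5.32e-09, adjusted p = 0.271 with an estimated correlation; 10 adjusted over the list alone). Among them STZ (AT1G27730), a zinc finger repressor gene, rose from 55.2 ± 0.60 to 1037 ± 90.0 RPKM, and WRKY40 (AT1G80840) from 12 ± 1.54 to 321 ± 27.9 RPKM. TCH4 (AT5G57560) and TCH3 (AT2G41100), chosen after their values were seen, reached 5393 ± 1847 and 4348 ± 394 RPKM from 87.4 ± 5.96 and 168 ± 29.9 RPKM. Of 36 genes of pattern-triggered immunity, 30 were higher and 1 lower (31 and 1 adjusted over the list alone), with a median of 2.37 (camera adjusted p = 8.32e-17, adjusted p = 0.271 with an estimated correlation). WRKY18 (AT4G31800) rose from 19.2 ± 0.50 to 682 ± 44.0 RPKM and the kinase gene MPK11 (AT1G01560) from 1.72 to 61.5 RPKM. The lower member was WRKY60 (AT2G25000), with a log2 change of -0.65, and the flagellin-induced kinase gene FRK1 (AT2G19190) was at 105 ± 28.2 and 102 ± 1.41 RPKM. Both were chosen after their values were seen, and WRKY60 lost its call without control replicate 2 (adjusted p = 0.058) or glutamate replicate 1 (adjusted p = 0.12) and when centred on the control genes (adjusted p = 0.070). No library was taken from seedlings moved to medium without glutamate.

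**Figure D2:**
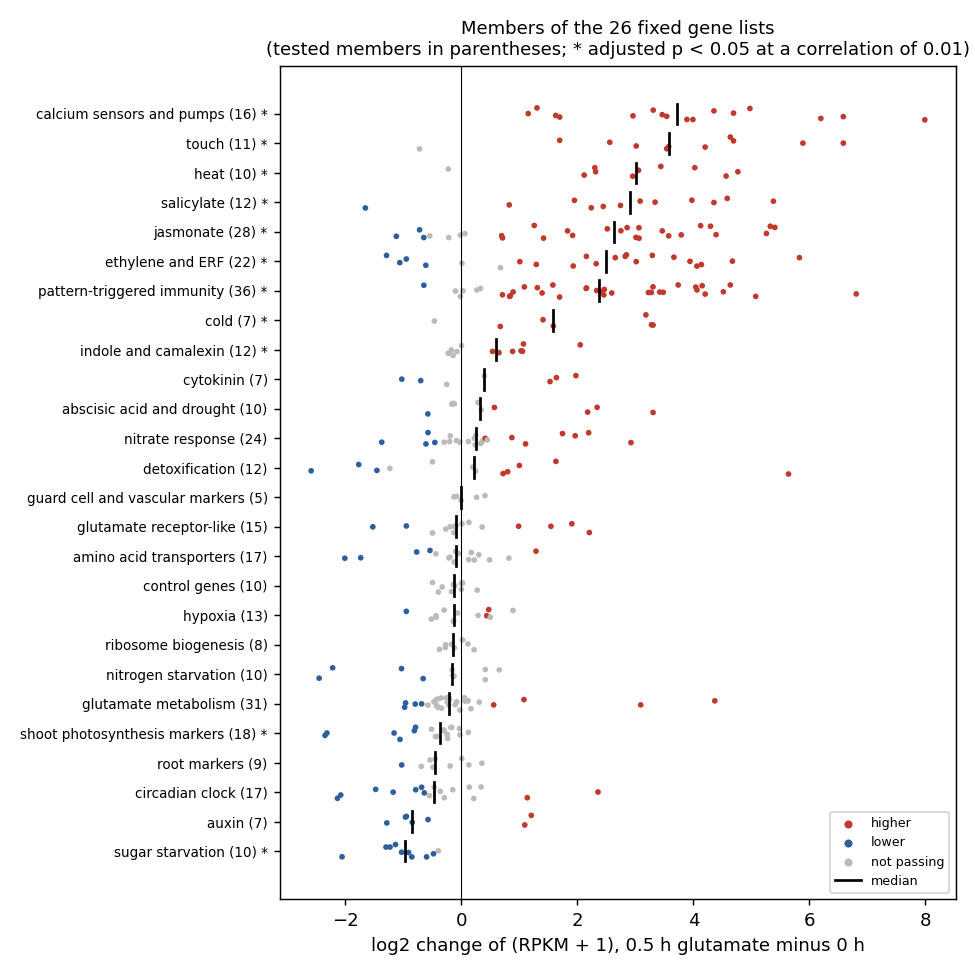
Log2 change of RPKM + 1 (horizontal) of each tested member of the 26 gene lists (vertical, ordered by median), 1 dot per gene, red if higher, blue if lower and grey if not passing, with the list median as a black bar. The medians run from -0.97 for sugar starvation to 3.72 for calcium sensors and pumps, and the control genes centre at -0.12, moving to 0.01 when centred on themselves.

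The jasmonate, ethylene and salicylate lists were higher at the preset correlation. In the jasmonate list 21 of 28 genes were higher and 3 lower (21 and 4 adjusted over the list alone), with a median of 2.63 (camera adjusted p = 7.56e-10, adjusted p = 0.271 with an estimated correlation). The biosynthesis genes AOC3 (AT3G25780) and LOX4 (AT1G72520) rose from 2.99 ± 0.06 to 168 ± 6.46 and from 1.36 ± 0.17 to 89.2 ± 2.45 RPKM, and the repressor gene JAZ5 (AT1G17380) from 0.477 to 58.3 RPKM. The 3 lower members, chosen after their values were seen, were LOX2 (AT3G45140), AOC1 (AT3G25760) and JAR1 (AT2G46370), which act in jasmonate synthesis and conjugation, with log2 changes of -0.72, -1.12 and -0.65. JAR1 lost its call without control replicate 1 (adjusted p = 0.083) or glutamate replicate 2 (adjusted p = 0.075). Of 22 genes of ethylene and ERF factors, 16 were higher and 4 lower (17 and 4 adjusted over the list alone), with a median of 2.49 (camera adjusted p = 7.39e-08, adjusted p = 0.271 with an estimated correlation). RRTF1 (AT4G34410) rose from 0.104 to 61.8 RPKM, with a shared-read fraction of 0.196 and a control level near the floor, at 4.4 and 2.4 reads. The ethylene synthesis gene ACS8 (AT4G37770) rose from 2.94 ± 0.10 to 59.6 ± 0.37 RPKM and the factor ERF6 (AT4G17490) from 15.0 ± 0.47 to 267 ± 29.5 RPKM. The lower members were the ethylene receptor genes ETR2 (AT3G23150) and ERS2 (AT1G04310), EBF2 (AT5G25350), which targets ethylene transcription factors for breakdown, and the factor ORA59 (AT1G06160), with log2 changes of -0.95, -0.61, -1.29 and -1.06. All but ETR2 were chosen after their values were seen, EBF2 had a shared-read fraction of 0.178, and ERS2 lost its call without control replicate 1 (adjusted p = 0.17), glutamate replicate 1 (0.0504) or glutamate replicate 2 (0.19), and also without the filter, with the median log2 ratio set to 0 or when centred on the control genes (0.066 to 0.092). In the salicylate list 11 of 12 tested genes were higher and 1 lower (11 and 1 adjusted over the list alone), with a median of 2.91 (camera adjusted p = 6.72e-08, adjusted p = 0.271 with an estimated correlation). A further 6 of its 18 members lay below the minimum mean and were not tested. GRX480 (AT1G28480), a glutaredoxin gene, rose from 3.01 ± 0.37 to 166 ± 0.38 RPKM. Of the salicylate receptor genes, NPR3 (AT5G45110) rose from 12.3 ± 1.02 to 133 ± 0.13 RPKM and NPR4 (AT4G19660), chosen after its value was seen, fell from 12.2 ± 0.95 to 3.21 ± 0.01 RPKM. PBS3 (AT5G13320), needed for salicylate synthesis, rose from 2.88 to 90.4 RPKM.

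Of 10 heat genes 9 were higher, with a median of 3.01 (camera adjusted p = 2.09e-06, adjusted p = 0.337 with an estimated correlation; 9 adjusted over the list alone). HSFA2 (AT2G26150), a heat shock factor gene, rose from 1.88 ± 0.43 to 67.6 ± 14.2 RPKM and DREB2A (AT5G05410) from 20.7 ± 3.63 to 167 ± 25.1 RPKM. MBF1C (AT3G24500) rose from 23.2 to 198 RPKM with a shared-read fraction of 0.138. Of 7 cold genes 6 were higher, with a median of 1.59 (camera adjusted p = 0.000996, adjusted p = 0.271 with an estimated correlation; 6 adjusted over the list alone). COR47 (AT1G20440) rose from 200 ± 29.1 to 1945 ± 267 RPKM, KIN1 (AT5G15960) from 0.324 to 11 RPKM and CBF1 (AT4G25490) from 0.922 to 4.78 RPKM. The control level of KIN1 rests on 8.0 and 1.0 reads and is uncertain. In the indole and camalexin list 7 of 12 genes were higher, with a median of 0.59 (camera adjusted p = 0.047, adjusted p = 0.713 with an estimated correlation; 7 adjusted over the list alone), among them MYB51 (AT1G18570), a regulator of indole glucosinolates, at 52.8 ± 0.47 and 224 ± 46.2 RPKM, CYP79B3 (AT2G22330) at 26.4 and 56.5 RPKM and CYP83B1 (AT4G31500) at 232 and 425 RPKM. With quantile normalization 5 were higher and 2 lower. That list call was lost without control replicate 2 (adjusted p = 0.14) or glutamate replicate 2 (0.058), and also without the filter, with a mean of at least 5, with quantile normalization, with the median log2 ratio set to 0 or with voom weights (adjusted p = 0.052 to 0.10). CYP83B1 missed the threshold with quantile normalization (adjusted p = 0.052). In the abscisic acid and drought list 4 of 10 genes were higher and 1 lower, the same counts as adjusted over the list alone, and the list did not pass (camera adjusted p = 0.10). NCED3 (AT3G14440), which limits abscisic acid synthesis, rose from 0.336 to 5.77 RPKM, the phosphatase gene HAI1 (AT5G59220) from 0.542 to 5.99 RPKM and RD29A (AT5G52310), also on the cold list, from 7.30 ± 3.25 to 78.9 ± 18.5 RPKM.

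Genes of nitrogen metabolism changed in both directions, and none of their 5 lists passed camera. In the nitrate response list 7 of 24 genes were higher and 4 lower (8 and 4 adjusted over the list alone; median 0.25, camera adjusted p = 0.10), and 1 was lower without control replicate 1 or glutamate replicate 2 and 2 without glutamate replicate 1. The nitrate reductase gene NIA2 (AT1G37130) rose from 26.4 ± 2.41 to 208 ± 39.0 RPKM, a log2 change of 2.93 ± 0.17. The nitrite reductase gene NIR1 (AT2G15620) rose from 8.43 ± 0.22 to 35.8 ± 2.07 RPKM and the transcription factor gene HHO3 (AT1G25550) from 46.3 ± 8.20 to 215 ± 35.9 RPKM. The largest fall in the list, chosen after its value was seen, was that of the factor TGA1 (AT5G65210), from 39.3 ± 5.42 to 14.6 ± 2.15 RPKM. In the nitrogen starvation list 4 of 10 tested genes were lower and 0 higher (4 lower and 3 higher adjusted over the list alone, median -0.15, camera adjusted p = 0.36). With the median log2 ratio set to 0 or when centred on the control genes, 3 were lower and 2 higher. The ammonium transporter genes AMT1;3 (AT3G24300) and AMT1;2 (AT1G64780) fell from 20.4 ± 2.44 to 2.91 ± 0.31 and from 15.5 ± 3.00 to 2.53 ± 0.21 RPKM, and the nitrate transporter gene NRT2.5 (AT1G12940) from 45.0 ± 10.3 to 21.3 ± 1.77 RPKM.

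Of 31 tested genes of glutamate metabolism, 4 were higher and 4 lower (3 and 4 adjusted over the list alone). Their median was -0.22, their mean 0.04 and the camera direction down, with an adjusted p of 0.43. This split depended on the setting: 3 were higher and 10 lower with quantile normalization, 3 and 12 with library totals, 3 and 7 without control replicate 2, and 3 and 2 without control replicate 1. GAD4 (AT2G02010), a glutamate decarboxylase gene, rose from 2.26 ± 0.30 to 66.4 ± 5.87 RPKM and GAD1 (AT5G17330), another, from 68.8 ± 0.42 to 147 ± 14.2 RPKM. PDH2 (AT5G38710), a proline dehydrogenase gene, rose from 1.01 ± 0.37 to 16.0 ± 0.14 RPKM. Of 15 tested glutamate receptor-like genes, 4 were higher and 2 lower, also when adjusted over the list alone. Their median was -0.09, their mean 0.23 and the camera direction up (adjusted p = 0.58), a direction that turned without the filter on low values. GLR1.2 (AT5G48400) rose from 5.73 ± 0.86 to 24.1 ± 0.06 RPKM, GLR2.5 (AT5G11210) from 2.89 ± 0.36 to 17.1 ± 3.76 RPKM, GLR2.8 (AT2G29110) from 0.896 to 4.53 RPKM and GLR1.3 (AT5G48410) from 4.53 to 9.97 RPKM. GLR3.5 (AT2G32390) and GLR3.4 (AT1G05200) fell by 1.52 ± 0.17 and 0.95 ± 0.15 on the log2 scale. GLR3.3 (AT1G42540) was at 12 ± 2.56 and 8.28 ± 2.17 RPKM and did not pass (adjusted p = 0.16), but passed without glutamate replicate 1 (adjusted p = 0.042). Of 17 amino acid transporter genes 1 was higher and 4 lower, also when adjusted over the list alone (median -0.10, camera adjusted p = 0.58), and 3 were higher and 3 lower when centred on the control genes. GDU1 (AT4G31730), linked to glutamine export, fell from 16.8 ± 1.01 to 3.42 ± 0.08 RPKM and CAT6 (AT5G04770) from 12.4 ± 1.48 to 3.02 ± 0.41 RPKM, while AAP5 (AT1G44100) rose from 22.0 ± 0.27 to 55.2 ± 2.32 RPKM.

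**Figure D3:**
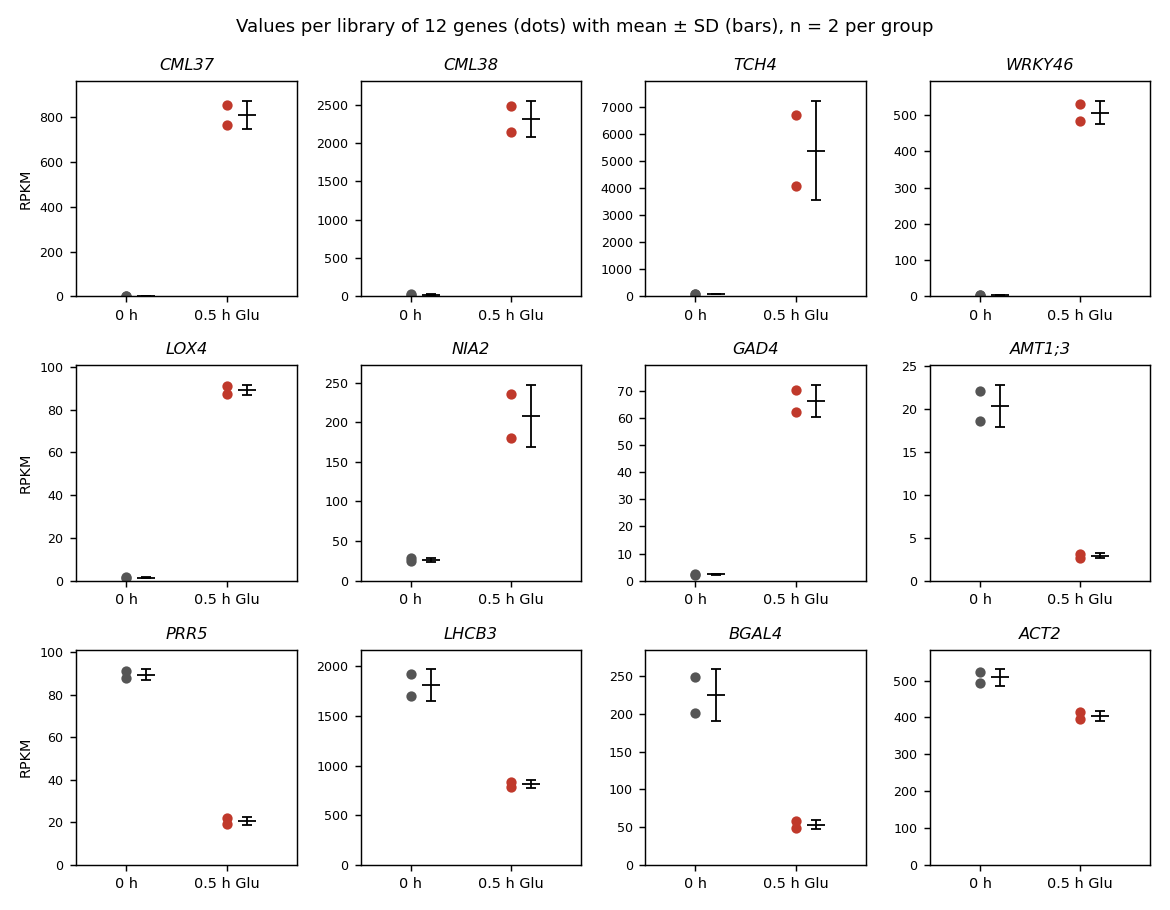
RPKM in each library (dots, vertical axes from 0) of 12 genes at 0 h (grey) and after 0.5 h of glutamate (red), with the mean ± SD of the 2 libraries beside them. In 11 of the 12 genes the change passed the test, for example NIA2 from 26.4 to 208 RPKM and AMT1;3 from 20.4 to 2.91 RPKM, and ACT2, at 509 and 405 RPKM, did not pass.

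Sugar starvation genes and shoot photosynthesis markers were the lists that fell. Of 10 sugar starvation genes 9 were lower, also when adjusted over the list alone, with a median of -0.97 (camera adjusted p = 6.53e-05, adjusted p = 0.271 with an estimated correlation). The beta-galactosidase gene BGAL4 (AT5G56870) fell from 225 ± 34.2 to 53.4 ± 6.33 RPKM and SEN1 (AT4G35770), a gene of darkened and ageing leaves, from 745 ± 34.3 to 318 ± 20.3 RPKM. BZIP1 (AT5G49450) fell from 84.3 to 37.9 RPKM, but all of its reads are marked as shared. Of 18 shoot photosynthesis markers 6 were lower (7 adjusted over the list alone) and the median was -0.36 (camera adjusted p = 0.00196, adjusted p = 0.417 with an estimated correlation). Of the 6 lower members 4 encode light-harvesting proteins. LHCB3 (AT5G54270) fell from 1813 ± 158 to 811 ± 40.3 RPKM, and LHCB1.1 (AT1G29920) and LHCB2.1 (AT2G05100) from 1994 ± 125 to 391 ± 33.2 and from 1672 ± 186 to 334 ± 25.7 RPKM, with shared-read fractions of 0.254 and 0.433. The other lower members, chosen after their values were seen, act in carbon fixation: RCA (AT2G39730), for Rubisco activase, and PRK (AT1G32060), for phosphoribulokinase, with log2 changes of -0.79 and -0.81. RCA lost its call without control replicate 1 (adjusted p = 0.080) or glutamate replicate 2 (0.11) and without the filter (0.083). RBCS1A (AT1G67090), for the small subunit of Rubisco, also chosen after its value was seen, was at 5958 ± 654 and 5288 ± 909 RPKM.

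Clock genes changed in both directions, more of them lower, and their list did not pass camera. Of 17, 2 were higher and 7 lower (3 and 7 adjusted over the list alone; median -0.47, camera adjusted p = 0.10), and the list passed as lower without control replicate 1 (adjusted p = 0.046) or glutamate replicate 2 (0.026). CDF1 (AT5G62430) rose from 4.27 ± 0.28 to 26 ± 2.04 RPKM, while RVE1 (AT5G17300) and PRR5 (AT5G24470) fell from 12.4 ± 0.39 to 2.05 ± 0.07 and from 89.6 ± 2.56 to 20.5 ± 1.96 RPKM. Of 7 tested auxin genes 2 were higher and 5 lower, also when adjusted over the list alone (median -0.84, camera adjusted p = 0.33). The root-branching factor LBD16 (AT2G42430) fell from 3.77 to 0.964 RPKM, and IAA2 (AT3G23030) and IAA19 (AT3G15540), repressors of auxin signalling, rose by 1.09 and 1.21 on the log2 scale. Of 7 cytokinin genes 3 were higher and 2 lower, also when adjusted over the list alone (median 0.40, camera adjusted p = 0.40). The response regulator genes ARR5 (AT3G48100) and ARR7 (AT1G19050) rose from 7.98 to 34.3 and from 12.3 to 40.6 RPKM, and ARR9 (AT3G57040) fell from 9.64 to 4.24 RPKM. Of 12 detoxification genes 5 were higher and 3 lower (5 and 4 adjusted over the list alone; median 0.22, camera adjusted p = 0.52), and the direction of the test turned without control replicate 2 (4 higher and 5 lower) or glutamate replicate 2. OM66 (AT3G50930), for a mitochondrial membrane protein, rose from 2.05 ± 0.30 to 151 ± 5.17 RPKM and the glutathione transferase gene GSTF8 (AT2G47730) from 401 ± 6.40 to 1244 ± 38.8 RPKM, while GSTU1 (AT2G29490) fell from 77.5 ± 4.40 to 22.1 ± 1.19 RPKM.

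Of 13 hypoxia genes 2 were higher and 1 lower (0 and 1 adjusted over the list alone). Their median was -0.13 and their mean -0.03 against a camera direction of up (adjusted p = 0.77), which turned without control replicate 2 (0 higher and 4 lower) or glutamate replicate 1. The rises of LBD41 (AT3G02550) and PCO1 (AT5G15120), 0.44 and 0.47 on the log2 scale, lost their calls when any library was left out, at adjusted p-values of 0.092 to 0.21 for LBD41 and 0.068 to 0.25 for PCO1. Of 9 tested root markers 1 was lower, also when adjusted over the list alone. It was TIP2;3 (AT5G47450), an aquaporin gene, which fell from 2.11 to 0.522 RPKM. The root median was -0.45 (camera adjusted p = 0.52), and that list passed as lower without control replicate 2 (4 lower, adjusted p = 0.043) and turned to up without control replicate 1 (adjusted p = 0.66). In limma, 0 of 5 guard cell and vascular markers were called (median -0.004, mean 0.09, camera direction up, adjusted p = 0.76), and 0 of 8 ribosome biogenesis genes (median -0.14, camera adjusted p = 0.67), also when adjusted over the lists alone, and in either list 0 had an unadjusted p under 0.05. Of the ribosome biogenesis genes 2 were called lower with quantile normalization and 1 with library totals. The camera direction turned for the first without control replicate 2 or with a mean of at least 5, and for the second without control replicate 1 or glutamate replicate 2. Of the 10 control genes 0 were called, also when adjusted over the list alone, and 2 had an unadjusted p under 0.05, with log2 changes from -0.49 to 0.27 (median -0.12). UBQ10 (AT4G05320) was at 1842 ± 209 and 1304 ± 79.1 RPKM (adjusted p = 0.059), with a shared-read fraction of 0.125, and ACT2 (AT3G18780) at 509 ± 22.5 and 405 ± 13.2 RPKM (adjusted p = 0.11). Both were called lower with quantile normalization (adjusted p = 0.015 and 0.011), as were 4 of the 10 control genes in all, and with library totals (adjusted p = 0.017 and 0.029), where 2 were.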

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

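The alternatives added after seeing the data were no further pseudocount, library totals, control-gene centring, genes with few shared reads, and voom weights. Counts within 1.5 times the reported ones are left out here except for ranges. Higher genes fell from 2888 to 1829 and lower genes from 2585 to 844 with a fold change of at least 2, by construction, and the genes lower after 0.5 h of glutamate to 1088 at an adjusted p under 0.01. Lower genes numbered 4364 with library totals and 1675 when centred on the control genes, because these move the median of all genes. The shared number of replicates gave a replicate block with 4445 higher and 5280 lower genes, including all 2888 and 2585 reported. It also called ACT2, UBQ10 and GLR3.3 lower and ATCG00950 higher, 13 genes of glutamate metabolism lower and 5 higher, 3 control genes lower and 1 higher, and 3 ribosome biogenesis genes lower and 1 higher. Same-numbered libraries deviated together across genes (r = 0.60, rho = 0.65). With 2 pairs and no label saying what a number marks, whether the libraries are paired cannot be told. Genes not called in the unpaired fit, control genes among them, are therefore not shown to be unchanged. Leaving out each library gave 2482 to 2780 higher and 1794 to 2085 lower genes, with the lone library of a group assumed to vary like the other group. It gave 8 to 9 higher lists and 2 to 3 lower lists. With the correlation estimated per list, 0 lists were higher and 0 lower (3 at an unadjusted p under 0.05), against 9 and 2 at the preset correlation. The smallest adjusted p was 0.271. That version has only 2 residual degrees of freedom, so it cannot tell whether correlation between genes accounts for the list results. The touch list, with an estimated correlation of -0.014, went from an unadjusted camera p of 8.19e-10 to 0.023. Fry, which does not compare a list with other genes, gave 4 lower lists, adding control genes (adjusted p = 0.031) and circadian clock (0.044), and 11 higher lists, adding nitrate response (0.044), abscisic acid and drought (0.0063) and cytokinin (0.030) and losing indole and camalexin (0.083). Of the 112 named genes, FRK1 turned positive with the median log2 ratio set to 0 (0.039), without control replicate 1 (0.26, against -0.29 without control replicate 2) and when centred on the control genes (0.12), and RBCS1A with quantile normalization (0.080). Neither was called in any of these, and the cause was not tested. Of 1991 values of named genes under other settings, these 4 included, 1945 kept direction and side of the threshold, 31 lost a call in 7 genes (16 of them in LBD41 and PCO1) and 11 gained one. Most named genes were picked for a large change or a small p, so these counts do not show how stable calls are in general. DESeq2 and edgeR, also planned, were not run, because the deposited values are RPKM and not raw counts, the case for which edgeR was planned. Voom was run on the recovered reads, some of which are fractional. Depth limits low genes: 3 reads per kb are 0.104 to 0.152 RPKM.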

Other observations

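The grouping by product name and the tests below were chosen after the data were seen, except those of intron number and of LHCB copies, whose outcomes were stated before they were computed. Genes were grouped by the product name of the reference annotation, and 216 families with at least 10 tested members were compared with the 17198 tested genes that have a product name, by a one-sided Fisher's exact test per direction over 432 tests. The cytochrome P450 subfamily CYP71B stood out among the lower genes: 15 of 17 members were lower, with a median log2 change of -1.19 (adjusted p = 1.36e-08), and 14 to 16 were lower under the 4 other scalings. CYP71B26 (AT3G26290) fell from 137 ± 40.9 to 26.6 ± 7.12 RPKM (SD, n = 2) and CYP71B2 (AT1G13080) from 49.8 ± 5.94 to 11.2 ± 1.24 RPKM. Of 11 GH3 genes, whose enzymes join hormones to amino acids, 9 were lower (adjusted p = 0.000113; 4 of the 11 were on fixed lists), among them DFL2 (AT4G03400) at 40.2 ± 1.51 and 8.64 ± 0.58 RPKM. The other 2, PBS3 and DFL1 (AT5G54510), rose, DFL1 from 4.25 to 11.1 RPKM. The NPH3 family of phototropism proteins had 11 of 20 members lower (adjusted p = 0.00135), and RPT2 (AT2G30520) fell from 249 ± 26.6 to 71.4 ± 3.57 RPKM.

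Among the higher genes, 28 of 51 TIR-NBS-LRR disease resistance genes, which encode intracellular immune receptors, were higher, with a median of 0.63 (adjusted p = 8.61e-08), and 25 to 30 under the other scalings. None of them was on a fixed list. AT5G58120 rose from 2.65 ± 0.08 to 49.5 ± 0.54 RPKM and AT5G41750 from 2.82 to 85.1 RPKM with a shared-read fraction of 0.167. VQ motif genes were higher in 14 of 22 cases (adjusted p = 9.63e-05) and arabinogalactan proteins in 12 of 22 (adjusted p = 0.00193), with AGP15 (AT5G11740) at 288 ± 22.5 and 2700 ± 571 RPKM and AGP2 (AT2G22470) at 14.1 ± 4.69 and 483 ± 91.3 RPKM. In all, 23 families passed as higher and 16 as lower, and of these 17 and 7 also passed under each of the 4 other scalings, the families named here among them. Of the 16 lower families, 10 passed with library totals and 10 when centred on the control genes. Members of a family can share reads and regulation, so these tests do not rest on independent genes.

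A hypothesis stated before the test was that higher genes have fewer introns. The intron number of a gene was taken as the lowest among its annotated transcripts. The 2869 higher genes with an intron number had a mean of 3.21 introns against 5.21 in uncalled genes of the same mean level, a difference of -2.0 (10000 permutations within 20 level bins, two-sided p = 0.0001, the smallest they can give), and 26.8% against 12.2% had none. The 2572 lower genes differed by -1.81 (permutation p = 0.0001), so a low intron number went with change in both directions. Among genes changed at least 2-fold the difference was -2.39 for higher and -3.13 for lower genes, the opposite order, and higher and lower genes were not tested against each other. Gene length, the number of annotated transcripts and family membership were not held fixed, and the counts come from the reference annotation.

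The pattern that most invites a second look is the joint rise of the touch, calcium and immunity lists, with a median log2 change of 2.96 over 57 genes. The 4 other scalings do not account for it, as the lowest median under them was 2.75. They put the median of all tested genes between -0.23 and 0.07, so they could not have removed a rise of this size. Handling or time of day at the transfer cannot be told apart from glutamate, because 0 libraries were sampled at 0.5 h without it. Touch genes are known to respond to handling. An effect of glutamate itself stays open as well, and a mock transfer would separate these.

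The light-harvesting members of the shoot markers changed by a median of -1.11 and the 4 RBCS members by -0.11. A smaller share of shoot RNA would lower both. The lowest RBCS change less 2 SE was -0.55, above the light-harvesting median, though RCA and PRK also fell. The light-harvesting changes ran from -2.35 to -0.45, so the weakest overlapped that bound. LHCB1.3 (AT1G29930), the most abundant of the LHCB1 and LHCB2 copies and chosen after its values were seen, changed by -0.51. It did not pass in limma (adjusted p = 0.054). A small loss of shoot RNA is therefore not excluded. Reads moving between LHCB copies would leave their sums level, but the summed reads of the 5 LHCB1 copies changed by -0.91 and those of the 3 LHCB2 copies by -2.04 on the log2 scale, with both glutamate libraries below both control libraries, and LHCB2.3 (AT3G27690), chosen after its values were seen and with a shared-read fraction of 6.6e-05, fell from 88.7 to 47.9 RPKM. With quantile normalization the light-harvesting changes ran from -2.58 to 0 and the RBCS changes from -0.58 to 0.080, with 1 of the 4 called lower, and with library totals from -2.54 to -0.64, all 6 called lower, and from -0.43 to -0.22, again with 1 called lower. A change in the control of these genes by glutamate, by the move or by time stays open and was not tested.

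The fall of ATCG01180 is a candidate for an artifact of read placement. ATCG00950, chosen after its values were seen, has the same length of 2.81 kb, and both loci have a maxMultiRatio of 1. ATCG00950 had 4474 and 1978 reads in the control libraries and 5182 and 2959 in the glutamate libraries, against 2237, 1978, 0 and 0 for ATCG01180. Summed over both loci, reads relative to the effective library size changed by -0.057 on the log2 scale, with the groups overlapping. Assignment of shared reads to a different locus would give this.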
